A study of Mus musculus with 6 samples.

How the data were processed

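Gene expression was measured in 6 libraries of the mouse PDAC line UN-KC-6141: 2 controls, 2 with CRISPR/Cas9 editing of Ezh2 and 2 of Eed. The source and cell type labels name a cell line, while the protocol text says that RNA came from liver tissue; the libraries were treated as the cell line. Libraries were made with the QuantSeq 3' FWD kit and sequenced as single-end reads. The protocol mentions the kit's optional molecular identifiers, and whether they were used is not given in the sources used here. The deposited signal values are read counts per gene scaled for library depth by the authors. The programs named per the submitters' processing notes are FastQC 0.11.9, STAR 2.7.3a, DESeq2 1.34.0 and R 4.1.3, with builds mm10 and GRCm38.p3. The counting program, the strand counted and the rule that chose the rows are not given in the sources used here.

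The table held 15777 rows. Every value was a whole multiple of its column's smallest step (100% within a tolerance of 0.01), and the steps matched median-of-ratios size factors, so whole reads could be recovered. The totals were 21533940 and 37202051 reads in control, 14014746 and 11510228 in Ezh2_KO and 12649407 and 15282440 in Eed_KO. A single read was worth between 0.4521 and 1.541 normalised counts. No row had fewer than 11 reads over the 6 libraries. Gene names turned to dates by a spreadsheet were found on 23 rows, and 2 rows shared the name 2-Mar; these kept their names. Coordinates came from GENCODE vM21 (GRCm38), in which 14552 symbols (92.2%) were found. Mitochondrial genes were under RefSeq names, so 0 of the 15 listed symbols matched; the 7 present took 0.632% to 1.33% of reads.

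Genes with a value of at least 10 in at least 2 libraries were tested (13376). limma 3.58.1 in R 4.3.3 was fitted to log2 of the value plus 1 with 3 group means over all 6 libraries and an intensity trend (residual df 3, prior df 2.51). Benjamini-Hochberg adjusted p under 0.05 counted as a call. Each knockout was compared with control and Eed_KO with Ezh2_KO. Calls in both knockouts were counted beside the number expected of independent lists, and the covariance of fold changes was set beside 50 simulations of unchanged groups that shared the same 2 controls. With 2 libraries per group no exact permutation test can pass. Of 33 gene lists (839 members in all), 29 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, beside camera with the correlation estimated. No camera call held with the estimated correlation. The p-values were adjusted over the lists of a comparison, and counts are given over all genes, with counts adjusted over the list alone beside them for most lists. Cdkn2a and Cdkn2b have no row in the table and were not analysed here. Folds against a group with no reads are lower bounds, set at 3 reads over the group, and folds from 1 to 3 reads have a 95% counting interval. That interval is exact (Clopper-Pearson) and conditions on the sum of reads.

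Named genes were Ezh2, Eed and Suz12 in every comparison, and for each knockout the 8 largest rises and 8 largest falls among calls with groups apart and a mean of at least 50 in the higher group. From each list whose camera test passed, or with at least 3 called members, came up to 3 called members with the smallest adjusted p in each comparison with control. The 6 calls shared by both knockouts with the largest and the 6 with the smallest mean change were also named, and the 6 largest rises and falls between knockouts by the criteria used against control. Predicted gene models were left out of the largest changes. Nfe2l2 was named by the series title. Members given without an SE were named after their values were seen, as were Lyz2, Csf1r and Trf.

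Alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, no filter, a mean of at least 20, TMM, equal totals, quantile normalization, no intensity trend, the 4 libraries compared alone, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, replicate numbers as a block, a log2 change of at least 1, fry, and each library left out in turn. A group left with a single library was assumed to vary like the others. Thinning to equal depth was added after seeing the data. The gene lists, the tests and the rule for named genes were also fixed before the data were examined. The pipeline was tested on simulated data with known changes. At a log2 change of 1 it recovered 1.52% in the Ezh2_KO comparison and 0% in the Eed_KO comparison, at 2 it recovered 56.7% and 46.3%, and at 3 it recovered 77.6% and 76.1%. In the Ezh2_KO comparison the genes recovered numbered 1, 38 and 52, beside 10 false calls among 13082 genes. In the Eed_KO comparison they numbered 0, 31 and 51, beside 6 false calls among 13072. Of 28 lists other than the one shifted, the list test called 1 in the Ezh2_KO comparison and 0 in the Eed_KO comparison. The simulated genes varied independently, so these numbers do not show how the list test behaves when genes vary together.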

Results

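The libraries came from UN-KC-6141, a mouse pancreatic ductal adenocarcinoma (PDAC) line with mutant Kras. There were 2 control libraries, 2 from cells edited in Ezh2 (Ezh2_KO) and 2 from cells edited in Eed (Eed_KO). Ezh2 encodes the methyltransferase of Polycomb repressive complex 2 (PRC2), which methylates histones at silenced genes, and Eed encodes the subunit that binds the methylated histone tail. Transcripts were counted from reads at their 3' ends. The counted reads came to 21533940 and 37202051 in control replicates 1 and 2, 14014746 and 11510228 in Ezh2_KO, and 12649407 and 15282440 in Eed_KO. Values are normalised read counts, given as the mean ± SD (n = 2 libraries) or for replicate 1 and then replicate 2, and changes are log2 fold changes ± SE from limma. Counting intervals and floors cover counting error only. The titles number the libraries of a group differently, and the labels do not say if these numbers stand for cultures or clones, so the p-values measure only the spread between these samples.

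Libraries of a group lay closer to each other than to the other groups along the first 2 principal components, which held 50.2% and 28.6% of the variance. Across genes, which are not independent replicates, the Pearson correlation between the 2 libraries was 0.929 in control, 0.945 in Ezh2_KO and 0.958 in Eed_KO. The controls were the least alike, with 1134 genes at least 4-fold apart, against 698 in Ezh2_KO and 459 in Eed_KO. Control replicate 2 held transcripts typical of myeloid cells: Lyz2, the macrophage lysozyme, was at 72.43 and 2911 in the controls, and Csf1r, a macrophage growth factor receptor, at 18.31 and 902.3. In reads scaled to the library total (RPM), the list of immune cell genes took 592 RPM in control replicate 2, against 73.4 in control replicate 1 and between 15.6 and 171 in the knockout libraries. In Eed_KO and control replicate 1 most of it came from Cd14, at 2084 and 2680 in Eed_KO and 1009 in control replicate 1. Lyz2 was at 13.01 and 10.57 in Eed_KO and Csf1r at 6.505 and 12.68. The list of fibroblast genes took 575 and 2350 RPM in control, 2320 and 8180 in Ezh2_KO and 820 and 594 in Eed_KO. Its members Col3a1, Pdgfrb and Mgp were at 1.356, 0.9041 and 0.4521 in control replicate 2, so other members made up its RPM there. In Ezh2_KO replicate 1 they were at 8999, 1310 and 33.06.

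Each knockout group had the lowest counts of its own target. Ezh2 (chromosome 6, 47530139 to 47595341 on GRCm38) was at 3155 ± 455 in control, 592.2 ± 383 in Ezh2_KO and 2000 ± 324 in Eed_KO. It fell by 2.57 ± 0.46 in Ezh2_KO (limma adjusted p = 0.0232, lower in 2 of 2 libraries). The call of Ezh2, Ezh2_KO minus control, was lost without control replicate 1 and without either Eed_KO library. Its fall was at least 1.86 in all 6 fits that left out a library. Here and below, leaving out a library of the group not compared cannot change the fold change. It alters only the variance estimate and its degrees of freedom. In Eed_KO, Ezh2 differed from control by -0.66 ± 0.46 (limma adjusted p = 0.393). Eed (chromosome 7, 89954654 to 89980983) was at 710.5 ± 0.8 in control, 468.4 ± 87 in Ezh2_KO and 68.58 ± 20.8 in Eed_KO. It fell by 3.39 ± 0.29 in Eed_KO (limma adjusted p = 0.0171), a call lost without either Eed_KO library (largest adjusted p = 0.18), and differed by -0.61 ± 0.29 in Ezh2_KO (adjusted p = 0.19). Suz12 (chromosome 11, 79993106 to 80034123), which encodes the third core PRC2 subunit, fell by 0.84 ± 0.14 in Ezh2_KO (limma adjusted p = 0.0203), a call lost without either library of either knockout (largest adjusted p = 0.0878). In Eed_KO it differed by -0.66 ± 0.14 (adjusted p = 0.0559). Reads at transcript 3' ends need not cover the edited part of a gene, so these counts do not check the edits.

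**Figure D1:**
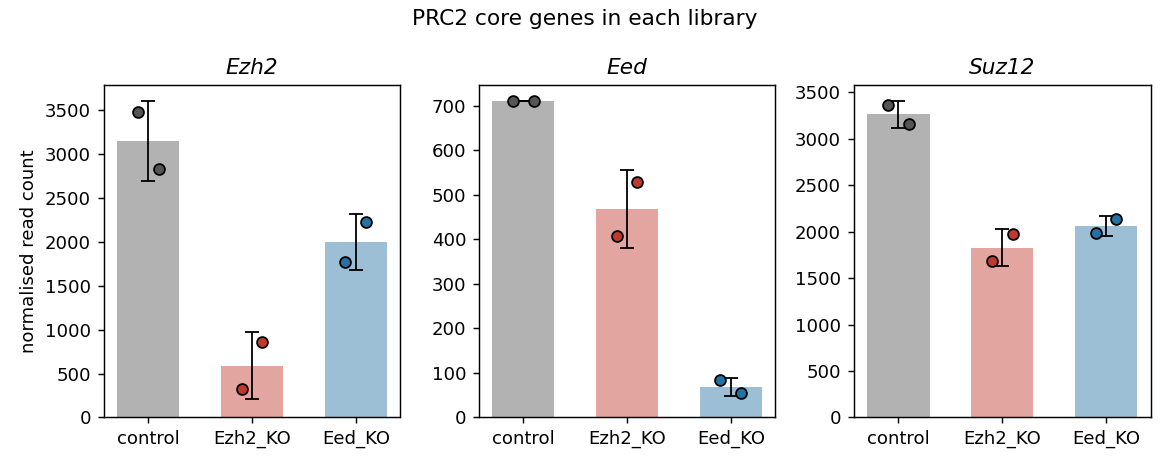
Normalised read counts of Ezh2, Eed and Suz12; bars are group means, error bars the SD (n = 2) and points the libraries. Ezh2 was lowest in Ezh2_KO (322 and 863) and Eed lowest in Eed_KO (83.3 and 53.9).

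The comparison of Ezh2_KO with control asks how loss of EZH2 affects the transcriptome of PDAC cells. Ezh2_KO cells had lower epithelial, duct and classical-subtype transcripts and higher mesenchymal, fibroblast, Hox and Wnt pathway transcripts, by list tests that did not pass with an estimated correlation (adjusted p = 0.206 to 0.342). Some members did not follow, with 8 of 19 epithelial genes lower and 2 higher, and 5 of 14 duct cell genes lower. Hnf4a and Hnf1a, transcription factors of endodermal epithelia, went from 4442 ± 1020 and 745 ± 122 in control to 6.162 ± 8.71 and 0.7703 ± 1.09. Col3a1, a fibrillar collagen, went from 6.648 ± 7.48 to 25680 ± 23600, and Fn1, the gene of fibronectin, from 12670 ± 2780 to 217700 ± 100000. Of 13376 genes tested, limma called 1375 higher and 1021 lower, 794 and 321 of them at least 4-fold. The counts of genes higher, Ezh2_KO minus control, and genes lower, Ezh2_KO minus control, were 342 and 263 without Ezh2_KO replicate 1, without replicate 2 they were 267 and 216, without Eed_KO replicate 1 they were 557 and 262, and without replicate 2 they were 568 and 259. They were 566 and 259 when the fit held only the 4 libraries compared, and 2174 and 1834 with DESeq2. After quantile normalization falls outnumbered rises, with 47.8% of 2377 calls higher.

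The largest rises among genes with a mean of at least 50 were those of Col3a1 (11.79 ± 1.23), Fstl1, which encodes a secreted glycoprotein (10.52 ± 0.79), and Peg3, a paternally expressed imprinted gene (10.01 ± 0.91). The others were Chst2, a sulfotransferase (11.24 ± 1.68), Scn5a, a sodium channel (10.82 ± 1.3), Timp3, a metalloproteinase inhibitor (10.4 ± 1.78), Myh10, a non-muscle myosin (9.92 ± 2.32), and Hhip, which encodes a hedgehog-binding protein (9.83 ± 1.4). The largest falls were those of Hnf4a (-10.23 ± 1.16), Krt23, a keratin (-10.34 ± 0.42), Anxa13, an annexin (-10.25 ± 0.65), Il5ra, the interleukin 5 receptor alpha chain (-9.71 ± 0.98), Gimd1 (-9.64 ± 0.42), Acan, the proteoglycan aggrecan (-9.6 ± 1.17), Pklr, a pyruvate kinase (-9.46 ± 0.4), and Hnf1a (-8.86 ± 0.53). Pklr, Gimd1 and Krt23 had no reads in Ezh2_KO, so they were at least 339-fold, 387-fold and 631-fold lower, against a floor of 3 reads over the group. All 16 passed the limma threshold, with adjusted p from 0.00173 (Pklr, Gimd1 and Krt23) to 0.0414 (Myh10), each in 2 of 2 libraries. The 8 falls and the rises of Col3a1, Fstl1 and Peg3 held in all 6 fits that left out a library. Chst2, Scn5a, Timp3, Myh10 and Hhip lost the call without either Ezh2_KO library, Timp3 also without either Eed_KO library and Myh10 without either control (largest limma adjusted p = 0.166).

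Epithelial genes were lower as a group. Of 19 tested, 8 fell and 2 rose (median -1.36), or 10 and 2 adjusted over the list alone, with camera adjusted p = 4.78e-04, but adjusted p = 0.206 with an estimated correlation. Those that fell included Lsr, a tricellular junction protein (-8.3 ± 0.65), Esrp2, an epithelial splicing factor (-4.71 ± 0.41), Spint2, a protease inhibitor (-3.37 ± 0.29), and Krt19, a duct keratin (-2.43 ± 0.26). Their limma adjusted p ran from 0.0037 to 0.00701, and all held in every fit that left out a library. The members that rose were Jup, plakoglobin of cell junctions (0.85), and Spint1, a protease inhibitor (3.88). Without Eed_KO replicate 1 or 2 or without Ezh2_KO replicate 1, 0 epithelial genes rose by limma, and without either control 1 did. Before adjustment, 2 rose at p under 0.05 and 10 fell. The list of duct cell genes fell as well, with 5 of 14 lower (6 adjusted over the list alone, median -2.08, camera adjusted p = 0.0125, adjusted p = 0.276 with an estimated correlation). Muc1, a membrane mucin, fell by 6.07 ± 0.39 and Hnf1b, a duct transcription factor, fell by 1.73 ± 0.2; the Hnf1b call was lost without Ezh2_KO replicate 2 (limma adjusted p = 0.0517), when 2 members fell.

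Classical-subtype pancreatic cancer genes, which mark better differentiated tumours, fell too. Of 21 tested, 11 fell and 0 rose by limma, and 0 rose before adjustment or with edgeR or DESeq2. All 11 also passed adjusted over the list alone. The median was -2.72 (-2.85 with genes at the floor at their bound), with camera adjusted p = 1.54e-05 and adjusted p = 0.206 with an estimated correlation. Hnf1a was 1100-fold lower (95% counting interval 198 to 43600, from 1 read), Foxa2, a pioneer factor of endoderm, fell by 2.34 ± 0.15, and Anxa10, an annexin, was at least 102-fold lower. These 3 calls held in all 6 fits that left out a library, with limma adjusted p between 0.0202 and 0.0288 at most. The count was 7 without any one of the 4 knockout libraries.

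Mesenchymal genes moved the other way. Of 21 tested, 13 rose and 0 fell by limma (16 and 0 adjusted over the list alone), and 0 fell before adjustment. The median was 3.04, with camera adjusted p = 7.66e-08 and adjusted p = 0.206 with an estimated correlation. Snai1, a repressor of epithelial genes, rose by 5.74 ± 0.58, Fn1 by 4.04 ± 0.4 and Sparc, a matrix glycoprotein, by 3.42 ± 0.31, all held in every fit that left out a library. The list count was 6 without Ezh2_KO replicate 1, 3 without replicate 2, and 5 without either Eed_KO library. Fibroblast genes, counted as markers of another cell type, rose in 8 of 11 (9 adjusted over the list alone; median 4.58, or 4.72 with genes at the floor at their bound; camera adjusted p = 3.53e-05, adjusted p = 0.24 with an estimated correlation). Pdgfrb, a growth factor receptor of mesenchymal cells, went from 1.248 ± 0.486 to 1898 ± 832. Mgp, a matrix protein, rose by 4.81 ± 0.75, a call lost without either Ezh2_KO library (limma adjusted p at most 0.067). The fibroblast count was 5 without either control library and 3 without either Ezh2_KO library. Fibroblast RPM went from 575 to 2350 between the controls and 2320 to 8180 between the Ezh2_KO libraries.

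**Figure D2:**
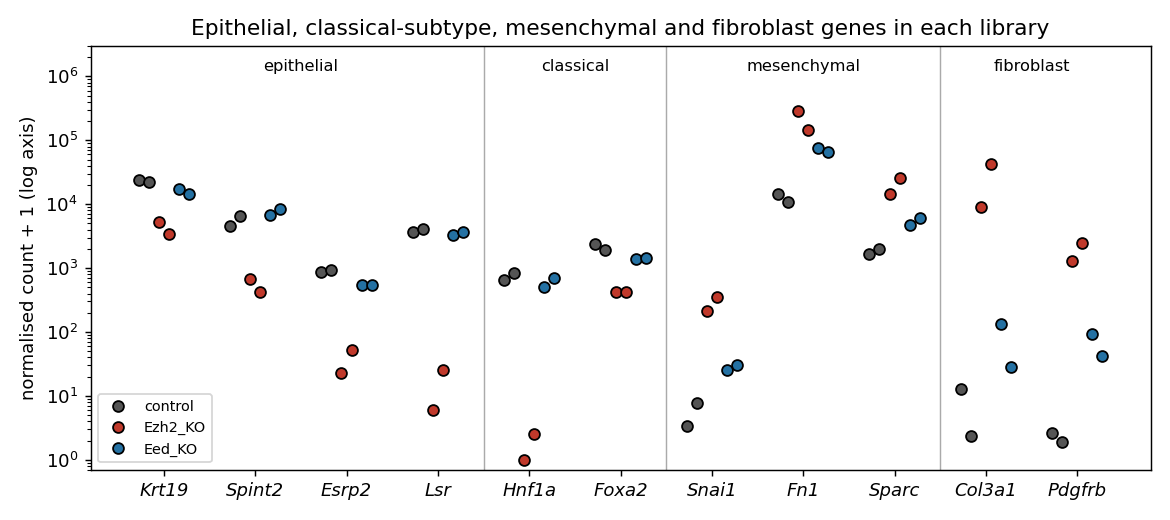
Normalised read count plus 1 (log axis) of 11 genes of the epithelial, classical-subtype, mesenchymal and fibroblast lists in each library; points are single libraries. The Ezh2_KO libraries lie below control for Lsr and Hnf1a and above it for Snai1 and Pdgfrb.

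Hox genes, which set positional identity in the embryo and are classic Polycomb targets, were the list with the smallest camera p. Of 31 tested, 20 rose and 0 fell by limma (24 and 0 adjusted over the list alone), and 0 fell before adjustment. The median was 4.68 (5.29 with genes at the floor at their bound), with camera adjusted p = 1.45e-11 and adjusted p = 0.276 with an estimated correlation. Hoxc8 was at least 189-fold higher, Hoxc9 345-fold (95% counting interval 117 to 1680, from 3 reads) and Hoxb4 79.6-fold, and these 3 calls held in all 6 fits that left out a library. By cluster, the summed counts of Hoxb (chromosome 11, 96194316 to 96354012) were 36.6 and 8.14 in control and 2969 and 4774 in Ezh2_KO. Those of Hoxc (chromosome 15, 102921103 to 103036852) were 14.3 and 1.36 against 816 and 1334, and those of Hoxd (chromosome 2, 74668310 to 74748442) were 0 and 0 against 217 and 535. Hoxa (chromosome 6, 52155590 to 52260880) was already at 1010 and 441 in control and at 1489 and 2161 in Ezh2_KO, with 2 of its 10 genes called. The Hox genes called were 9 without Ezh2_KO replicate 1, 4 without replicate 2 and 13 without either Eed_KO library. The counting strand was not given, so reads of Hox antisense transcripts may be among these counts.

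**Figure D3:**
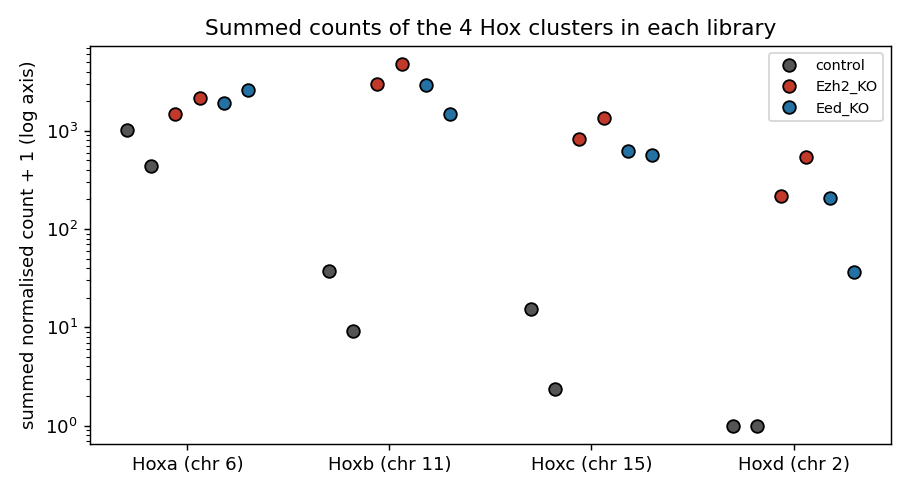
Summed normalised counts plus 1 (log axis) of the 4 Hox clusters in each library; points are single libraries. Hoxb, Hoxc and Hoxd lie higher in all 4 knockout libraries than in both controls.

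Other developmental genes rose with them. In the list of Polycomb-target developmental regulators 17 rose and 4 fell of 56 (21 and 4 adjusted over the list alone; median 2.12; camera adjusted p = 2.57e-04, adjusted p = 0.276 with an estimated correlation). Foxd1, a forkhead factor, rose by 6.15 ± 0.63 and Lhx6, a LIM homeobox factor, by 4.7 ± 0.51, while En1, a homeobox repressor, fell by 4.48 ± 0.35. Lhx6 lost the call without Ezh2_KO replicate 2 (limma adjusted p = 0.0529). The list counts were 2 higher and 2 lower without either Ezh2_KO library, and 8 and 10 higher without Eed_KO replicate 1 and 2, with 2 lower in each. Of 17 Wnt pathway genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone; median 3.98, or 4.64 with genes at the floor at their bound; camera adjusted p = 7.4e-05, adjusted p = 0.342 with an estimated correlation). Sfrp2, a secreted Wnt antagonist, was at least 95.4-fold higher, Lgr5, a stem cell receptor, rose by 6.08 ± 0.6 and Axin2, a feedback inhibitor, by 5.81 ± 0.5, and Rnf43, a ligase that removes Wnt receptors, fell (-2.65). Without Ezh2_KO replicate 1 and 2, 5 and 4 Wnt pathway genes rose. By limma 1 fell without control replicate 2 and 0 in the other 5 such fits (1 fell before adjustment with all libraries). TGF-beta and BMP pathway genes rose in 6 of 21 (7 adjusted over the list alone; median 1.21; camera adjusted p = 8.89e-04, adjusted p = 0.206 with an estimated correlation): Bmp2 by 3.87 ± 0.38, Tgfb3 by 3.8 ± 0.29 and Gdf15, a stress-induced ligand, by 2.99 ± 0.31 (limma adjusted p = 0.0502 without Ezh2_KO replicate 1). Among endocrine and neuronal genes 4 of 10 rose (4, and 1 lower, adjusted over the list alone; median 2.96; camera adjusted p = 0.0162, adjusted p = 0.306 with an estimated correlation): Map2 by 5.99 ± 0.55, Uchl1 by 4.59 ± 0.4, Tubb3 by 4.3 ± 0.39 and Ncam1 by 3.15, all genes of neurons. The camera call of the list Endocrine and neuronal genes, Ezh2_KO minus control, was lost without Ezh2_KO replicate 1 (adjusted p = 0.0892).

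The series title names a loop of NRF2 and EZH2. NRF2, encoded by Nfe2l2, drives antioxidant genes. Nfe2l2 itself was at 5236 ± 1700 in control, 4643 ± 1820 in Ezh2_KO and 4374 ± 449 in Eed_KO and passed in neither comparison (limma adjusted p = 0.727 and 0.703). NRF2 targets were lower in Ezh2_KO: of 36 tested, 12 fell and 0 rose by limma, or 15 and 2 adjusted over the list alone, and 17 fell and 2 rose before adjustment. The median was -0.35, with camera adjusted p = 9.58e-04 and adjusted p = 0.306 with an estimated correlation. Gclc and Gclm, the subunits of the first enzyme of glutathione synthesis, fell by 2.02 ± 0.25 and 1.56 ± 0.19, and Me1, an NADPH-producing malic enzyme, by 1.77 ± 0.13. Gclc and Me1 held in all 6 fits that left out a library; Gclm lost the call without either Ezh2_KO library (limma adjusted p at most 0.0581). The NRF2 targets that fell were 4 without Ezh2_KO replicate 1, 2 without replicate 2 and 5 without either Eed_KO library.

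**Figure D4:**
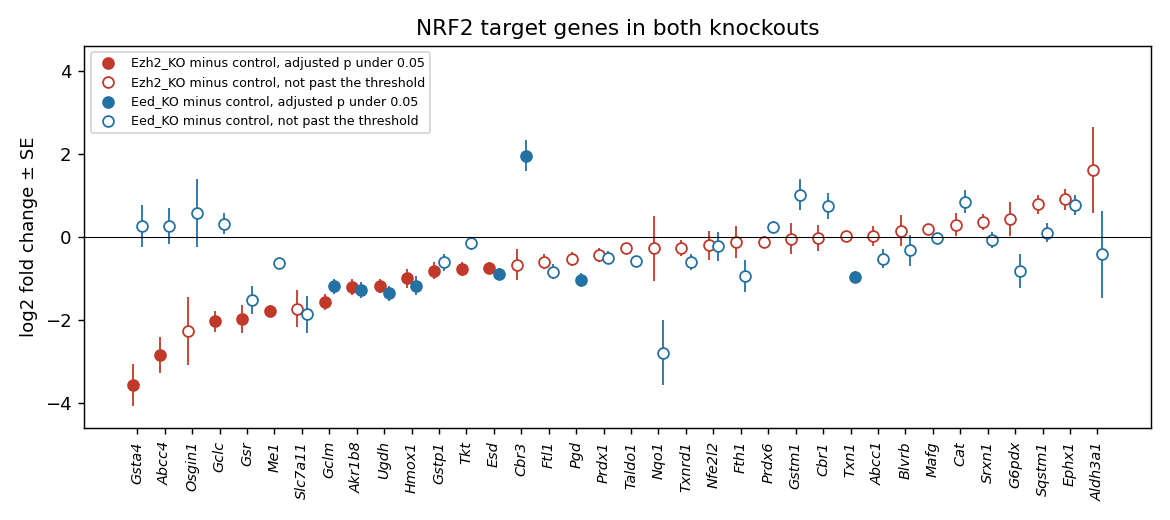
Log2 fold change ± SE of the 36 NRF2 target genes tested (Nfe2l2 included) in Ezh2_KO (red) and Eed_KO (blue) against control; filled points passed the limma threshold. In Ezh2_KO 12 fell, and in Eed_KO 7 fell and 1 rose.

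Lists of growth and metabolism had smaller shifts downward. Proliferation genes fell in 6 of 37 (7 adjusted over the list alone; median -0.35; camera adjusted p = 0.00128, adjusted p = 0.45 with an estimated correlation), among them Rrm2, a ribonucleotide reductase subunit (-1.22 ± 0.22), Mybl2, a cell cycle factor (-0.89 ± 0.19), and Mcm7, a replication helicase subunit (-0.79 ± 0.15). Cholesterol synthesis genes fell in 5 of 20 (5 adjusted over the list alone; median -0.57; camera adjusted p = 0.00128, adjusted p = 0.45 with an estimated correlation), with the enzymes Fdps (-1.35 ± 0.21), Lss (-1.11 ± 0.21) and Dhcr24 (-1.06 ± 0.16). Cytosolic ribosomal protein genes fell in 2 of 59, Rps12 (-0.79 ± 0.19) and Rpl38 (-0.72 ± 0.14), and in 0 adjusted over the list alone (median -0.22; camera adjusted p = 0.00128, adjusted p = 0.547 with an estimated correlation). Without any one of the knockout libraries, 0 proliferation genes and 0 ribosomal genes were called by limma, and 0 ribosomal genes without control replicate 1; before adjustment 11 and 9 fell, edgeR called 4 and 3, and DESeq2 8 and 11. The proliferation count was 2 without control replicate 1, and the cholesterol count was 3 without it, 1 and 0 without Ezh2_KO replicates 1 and 2 and 2 without either Eed_KO library. Reads of ribosomal pseudogenes may be counted with their genes.

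The comparison of Eed_KO with control asks the same of a second PRC2 subunit. Eed_KO cells had higher Hox, developmental and Wnt pathway transcripts, called in 13 of 31, 8 of 56 and 5 of 17 genes, by list tests that did not pass with an estimated correlation (adjusted p = 0.385 to 0.396). Hmgcs2, the ketone body enzyme, went from 6.329 ± 8.95 in control to 4256 ± 3650, and Zfp503, a zinc finger repressor, from 1.356 ± 1.92 to 1066 ± 85.3. Limma called 647 genes higher and 191 lower, 421 and 16 of them at least 4-fold. Limma called 0 genes without Eed_KO replicate 1 (2150 at an unadjusted p under 0.05, smallest adjusted p = 0.165) and 0 without replicate 2 (1975, smallest adjusted p = 0.18). The changes stayed large in those fits: without Eed_KO replicate 1 and then 2, Hoxc9, Eed_KO minus control, was 7.16 and 7.21, Fstl1, Eed_KO minus control, 8.28 and 8.76, and Eed, Eed_KO minus control, -3.7 and -3.08. The genes higher, Eed_KO minus control, and genes lower, Eed_KO minus control, were 149 and 7 without Ezh2_KO replicate 1, 141 and 7 without replicate 2, and 1182 and 454 without control replicate 2. Without control replicate 1, 92 were lower. They were 216 and 45 with edgeR, 125 and 7 when the fit held only the 4 libraries compared, and 1669 and 1156 with DESeq2.

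The largest rises in Eed_KO were those of Hmgcs2 (9.84 ± 1.36), Zfp503 (9.11 ± 0.88), Clca1, which encodes a secreted goblet cell protein (8.69 ± 0.72), Nepn, a small leucine-rich proteoglycan (8.59 ± 0.87), Fstl1 (8.52 ± 0.79), Col14a1, a fibril-associated collagen (8.25 ± 0.69), Rerg, a Ras-like growth inhibitor (8.17 ± 0.94), and Tmtc1 (8.06 ± 0.72). Col14a1 and Rerg had no reads in control and were at least 387-fold and 352-fold higher. The largest falls were those of Eda2r, a TNF receptor family member (-5.6 ± 0.66), Lilr4b (-5.46 ± 0.76), Tmem252 (-4.59 ± 0.8), Bcl2l15 (-4.25 ± 0.81), Mrc1, the mannose receptor (-4.02 ± 0.43), Ptpn22, a lymphoid phosphatase (-3.62 ± 0.71), Eed (-3.39 ± 0.29) and C3ar1, a complement receptor (-3.38 ± 0.36). Mrc1 was at 3874 and 1652 in the controls, so it was not higher in the control library that held myeloid transcripts. Lilr4b has a near-identical neighbour, Lilrb4a, which may share reads with it. Their limma adjusted p ran from 0.0171 to 0.0477, each in 2 of 2 libraries. All 16 lost the call without either Eed_KO library (largest adjusted p = 0.263). Hmgcs2, C3ar1, Mrc1, Eda2r, Tmem252, Lilr4b, Ptpn22 and Bcl2l15 also lost it without either Ezh2_KO library, the last 5 without control replicate 1, and Ptpn22 and Bcl2l15 without control replicate 2.

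Hox genes were higher here too: 13 of 31 rose and 0 fell by limma (22 and 0 adjusted over the list alone), and 0 fell before adjustment. The median was 4.21 (4.45 with genes at the floor at their bound), with camera adjusted p = 9.67e-12 and adjusted p = 0.385 with an estimated correlation. Hoxa13 rose by 7.56 ± 0.78, Hoxc9 by 7.19 ± 0.39 and Hoxc8 by 5.43 ± 0.49. The cluster sums in Eed_KO were 2934 and 1464 for Hoxb, 617 and 559 for Hoxc, 207 and 35.9 for Hoxd and 1905 and 2611 for Hoxa. Of 56 Polycomb-target developmental regulators, 8 rose and 0 fell by limma (17 and 1 adjusted over the list alone; 22 and 1 before adjustment; median 1.96, or 2.1 with genes at the floor at their bound; camera adjusted p = 1.33e-05, adjusted p = 0.385 with an estimated correlation). Foxd1 rose by 7.05 ± 0.63, Barx2, a homeobox factor, by 6.47 ± 0.75 and Tbx2, a T-box repressor, by 4.31 ± 0.52. Wnt pathway genes rose in 5 of 17 (7 adjusted over the list alone; median 2.41; camera adjusted p = 0.00109, adjusted p = 0.396 with an estimated correlation): Sfrp2 by at least 205-fold, Lgr5 by 4.1 ± 0.6, Tcf7 by 1.6 ± 0.23, Axin2 by 3.35 and Wnt6 by 4.42. TGF-beta and BMP pathway genes rose in 5 of 21 (7 adjusted over the list alone; median 0.95; camera adjusted p = 0.00804, adjusted p = 0.385 with an estimated correlation), with Bambi, a pseudoreceptor (4.54 ± 0.46), Tgfb3 (2.5 ± 0.29) and Skil, a SMAD repressor (0.98 ± 0.16). YAP target genes rose in 3 of 16 (5 adjusted over the list alone; median 0.59; camera adjusted p = 0.00904, adjusted p = 0.385 with an estimated correlation): Arhgef17 by 2.56 ± 0.33, Cyr61 by 2.52 ± 0.32 and Ctgf by 1.96 ± 0.36. Without either Eed_KO library, limma called 0 members of these 5 lists; without either Ezh2_KO library it called 3, 2, 1, 1 and 0, and without control replicate 1 it called 2 Wnt pathway genes and 2 YAP target genes.

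The epithelial list had rises alone in Eed_KO. Of 19, 4 rose and 0 fell by limma (6 and 0 adjusted over the list alone; 7 and 0 before adjustment; median 0.86), and the camera test did not pass (adjusted p = 0.0502). The members that rose were Epcam, an adhesion molecule (4.36), Esrp1, an epithelial splicing factor (6.51 ± 0.93), Spint1 (6.15 ± 0.79) and St14, the protease matriptase (4.04 ± 0.58). Duct cell genes had 1 of 14 higher, Onecut1, a duct transcription factor (6.57 ± 1.17), and 1 adjusted over the list alone (median 0.92; camera adjusted p = 0.0399, adjusted p = 0.385 with an estimated correlation). The camera call of the list Duct cell genes, Eed_KO minus control, was lost without control replicate 1 (0.0763), without Eed_KO replicate 2 (0.0952) and without an intensity trend (0.0597). Limma called 0 epithelial and 0 duct genes without either Eed_KO library, 1 and 0 without either Ezh2_KO library, and 1 and 2 without control replicate 1; 2 duct genes were called without control replicate 2.

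NRF2 targets were also lower in Eed_KO, though the members called were the same only in part. Hmox1, Gclm, Ugdh, Akr1b8 and Esd were called lower in both knockouts, and Pgd and Txn1 in Eed_KO alone. Gclc, Me1, Tkt, Gsr, Gsta4, Gstp1 and Abcc4 were called lower in Ezh2_KO alone. A call in 1 comparison alone is not a tested difference between the knockouts. In the direct limma test, 5 of the 36 NRF2 targets were higher and 1 lower in Eed_KO than in Ezh2_KO. Gclc differed from control by 0.32 in Eed_KO, and Txn1 by 0.02 in Ezh2_KO. Of 36, 7 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.5; camera adjusted p = 8.28e-04, adjusted p = 0.385 with an estimated correlation). For the list NRF2 targets, Eed_KO minus control, adjusted p was 0.0507 after quantile normalization. Ugdh, a glucuronate pathway enzyme, fell by 1.35 ± 0.18, Akr1b8, an aldose reductase-like enzyme, by 1.28 ± 0.19 and Txn1, thioredoxin, by 0.96 ± 0.14, while Cbr3, a carbonyl reductase, rose (1.96). Without control replicate 1 or either Eed_KO library, limma called 0 NRF2 targets (16 fell and 4 rose before adjustment in the full fit, edgeR called 2 and DESeq2 17), and without either Ezh2_KO library 1. Proliferation genes fell in 2 of 37, Bub1, a mitotic checkpoint kinase (-0.91 ± 0.17), and Birc5, survivin (-0.86 ± 0.17), and in 0 adjusted over the list alone (median -0.53; camera adjusted p = 3.54e-07, adjusted p = 0.385 with an estimated correlation). Cytosolic ribosomal protein genes fell in 1 of 59, Rpl38 (-0.7 ± 0.14), and in 0 adjusted over the list alone (median -0.25; camera adjusted p = 1.39e-05, adjusted p = 0.521 with an estimated correlation). For the list Cytosolic ribosomal protein genes, Eed_KO minus control, adjusted p was 0.304 after quantile normalization. Among genes of the interferon response and antigen presentation, Irf1, a transcription factor induced by interferon, rose by 1.76 ± 0.28, the single call of 35, adjusted over the list alone too (median 1.21; camera adjusted p = 4.59e-04, adjusted p = 0.527 with an estimated correlation). Ugdh, Akr1b8, Txn1, Bub1, Birc5, Rpl38 and Irf1 each lost the call without control replicate 1 and without any one knockout library (largest limma adjusted p = 0.291). Without control replicate 2, 9 genes of the Interferon response and antigen presentation list and 3 NRF2 targets rose, and 6 proliferation genes and 2 ribosomal genes fell.

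The knockouts shared calls. Of the 647 genes higher in Eed_KO, 354 (54.7%) were also higher in Ezh2_KO, against 66.5 for independent lists, a number that leaves out the effect of the shared controls. Of the 191 lower, 106 (55.5%) were also lower in Ezh2_KO, against 14.6. Of the genes called higher in both, the 6 with the largest mean change were Fstl1, Hoxb9, Col16a1, Hoxb8, Zfp503 and Col12a1. Col16a1 and Col12a1, collagens of the extracellular matrix, went from 2.378 ± 1.11 and 8.373 ± 7.34 in control to 1569 ± 679 and 1291 ± 493 in Ezh2_KO and to 439.2 ± 9.97 and 1762 ± 337 in Eed_KO. Hoxb8 and Hoxb9 went from 2.786 ± 3.94 and 1.302 ± 0.716 to 767.7 ± 237 and 1907 ± 690 in Ezh2_KO and to 452.9 ± 261 and 517.3 ± 575 in Eed_KO. Of those called lower in both, the 6 with the largest mean fall were Lilr4b, Tmem252, Mrc1, C3ar1, Inpp4b and Zfp697. Inpp4b, a phosphoinositide phosphatase, was at 1715 ± 547, 126.7 ± 0.59 and 242.4 ± 69.3, and Zfp697 at 887.2 ± 142, 155.2 ± 39.7 and 302.5 ± 10.1. In Ezh2_KO, C3ar1 and Hoxb8 lost the call without either Ezh2_KO library and Hoxb9 without replicate 2 (largest limma adjusted p = 0.0601). In Eed_KO all 12 lost it without either Eed_KO library, Hoxb8, Hoxb9, Lilr4b, Tmem252, Mrc1, C3ar1, Inpp4b and Zfp697 without either Ezh2_KO library, and Hoxb9, Lilr4b, Tmem252 and Zfp697 without control replicate 1 (largest limma adjusted p = 0.244). In opposite directions there were 2 genes higher in Ezh2_KO and lower in Eed_KO, and 14 the other way, against 19.6 and 49.4 for independent lists.

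**Figure D5:**
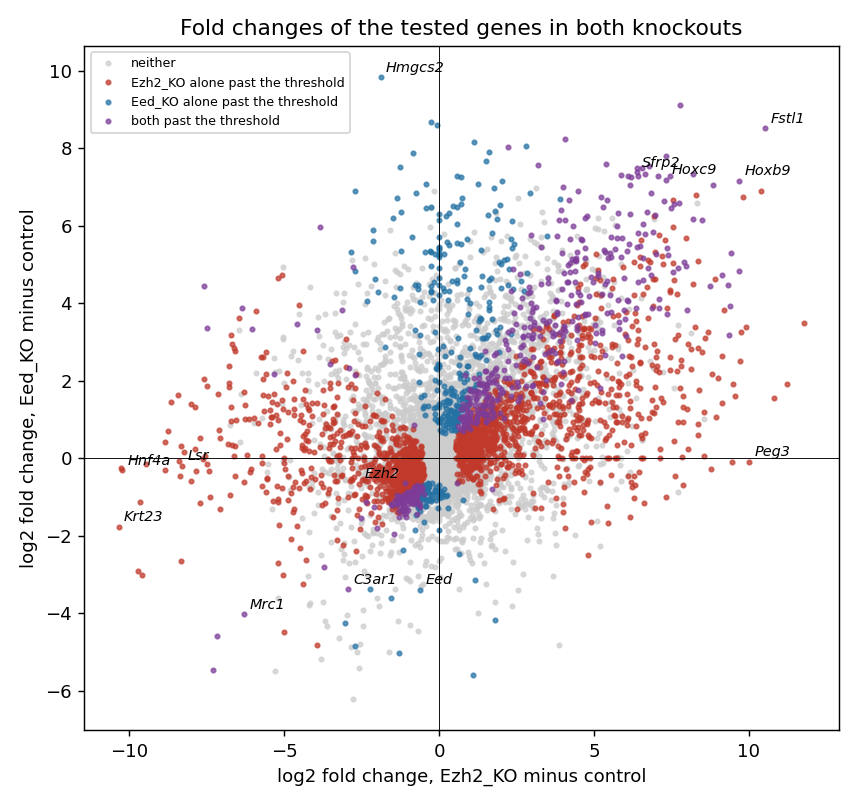
Log2 fold changes of the 13376 tested genes in Ezh2_KO (x axis) and Eed_KO (y axis) against control; colours give the comparisons in which limma called a gene. Fstl1 and Hoxc9 lie high on both axes, and Hnf4a and Lsr are low in Ezh2_KO alone.

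Both comparisons use the same 2 controls, which alone makes fold changes correlate. Across genes, Pearson's correlation of the fold changes was 0.449, and it was 0.654 ± 0.014 (SD) in 50 simulations of unchanged groups with shared controls. The simulated correlation follows from the spread within groups alone. Changes in either knockout add variance to the fold changes, so the lower observed value does not say how alike the knockouts are. The covariance was 1.13, against 0.391 ± 0.017 (SD) in those simulations. They drew each gene independently, so their SD leaves out noise that genes share, such as the differences between the controls described here. How far the shared controls alone could move the covariance therefore cannot be read from that SD. The 2 controls were not divided between the comparisons, so how many of the shared calls come from sharing them was not measured. Without either Eed_KO library limma shared 0 genes in each direction, while 354 and 106 were shared with all libraries, 154 and 31 with edgeR and 939 and 572 with DESeq2. The genes higher in both knockouts than control and the genes lower in both knockouts than control were 85 and 3 without Ezh2_KO replicate 1, 82 and 2 without replicate 2, and 751 and 273 without control replicate 2. Without control replicate 1, 59 were lower in both.

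The direct comparison of the knockouts asks where loss of the 2 subunits differed. Eed_KO cells had higher epithelial and classical-subtype transcripts than Ezh2_KO cells and lower mesenchymal ones. Limma called 12 of 19, 11 of 21 and 7 of 21 genes of these lists. The list tests did not pass with an estimated correlation (camera adjusted p = 0.0865 to 0.265). Lsr was at 14.87 ± 13.8 in Ezh2_KO and 3456 ± 291 in Eed_KO, beside 3938 ± 319 in control. Limma called 815 genes higher and 592 lower in Eed_KO than in Ezh2_KO, 522 and 249 at least 4-fold. The genes higher, Eed_KO minus Ezh2_KO, and genes lower, Eed_KO minus Ezh2_KO, were 21 and 12 without Eed_KO replicate 1, 211 and 36 without Ezh2_KO replicate 1, 184 and 18 without its replicate 2, and 1245 and 1064 or 1248 and 1075 without control replicate 1 or 2. Without Eed_KO replicate 2 limma called 1 higher and 0 lower, with 2002 at an unadjusted p under 0.05. With edgeR they were 479 and 303, and with DESeq2 1469 and 1379.

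Epithelial genes were higher in Eed_KO than in Ezh2_KO in 12 of 19 (16 adjusted over the list alone; median 3.81, or 3.39 with genes at the floor at their bound; camera adjusted p = 1.64e-09, adjusted p = 0.0865 with an estimated correlation). Classical-subtype pancreatic cancer genes were higher in 11 of 21 (17 adjusted over the list alone; median 4.05; camera adjusted p = 6.1e-11, adjusted p = 0.0865 with an estimated correlation). Duct cell genes were higher in 7 of 14 (10 adjusted over the list alone; median 3.6; camera adjusted p = 1.96e-05, adjusted p = 0.197 with an estimated correlation). Mesenchymal genes were lower in 7 of 21 (14 adjusted over the list alone; median -1.86; camera adjusted p = 2.69e-06, adjusted p = 0.265 with an estimated correlation), and fibroblast genes in 4 of 11 (8 adjusted over the list alone; median -4.84, or -4.22 with genes at the floor at their bound; camera adjusted p = 6.46e-05, adjusted p = 0.265 with an estimated correlation). Without Eed_KO replicate 1 or 2 limma called 0 members of these lists, except 1 fibroblast gene without replicate 1. Before adjustment 16, 17, 10, 14 and 9 members differed in the full fit, edgeR called 9, 10, 6, 6 and 3 of them, and DESeq2 called 15, 16, 10, 15 and 8. Without Ezh2_KO replicate 1 the counts were 8, 7, 3, 3 and 1, and without replicate 2 they were 6, 6, 3, 0 and 0. Without control replicate 1 or 2, 12 mesenchymal genes were lower. The list of hepatocyte genes took 592 and 1080 RPM in Eed_KO, most of them from Trf, transferrin, against 40 and 1.3 in Ezh2_KO and 61.3 and 35.9 in control.

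The largest rises in Eed_KO over Ezh2_KO were those of Dmbt1, a secreted mucosal glycoprotein (12.02 ± 0.51), Hmgcs2 (11.73 ± 1.36), Tmprss2, a transmembrane protease (10.85 ± 0.65), C3, complement component (10.23 ± 0.57), Myo15b (10.12 ± 0.71) and Dio3os (10.08 ± 1.49). Dio3os overlaps Dio3 on the other strand, and the strand counted was not given. The largest falls were those of Peg3 (-10.1 ± 0.91), Bnc2, a zinc finger gene of mesenchymal cells (-9.53 ± 0.8), Chst2 (-9.31 ± 1.68), Scn5a (-9.27 ± 1.3), Inhbb, an activin subunit (-9.04 ± 1.23), and Dynap (-8.69 ± 1.46). Their limma adjusted p ran from 0.00274 to 0.0309, each in 2 of 2 libraries of each group. All 12 lost the call without Eed_KO replicate 2, all but Dmbt1, Scn5a and Chst2 without replicate 1, 5 of them (Hmgcs2, Dio3os, Dynap, Scn5a and Chst2) without either Ezh2_KO library, and Inhbb and Bnc2 without Ezh2_KO replicate 2 (largest adjusted p = 0.194). Ezh2 differed by 1.91 ± 0.46 (limma adjusted p = 0.0595), Suz12 by 0.18 ± 0.14 (0.453) and Nfe2l2 by -0.03 ± 0.35 (0.962).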

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

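Of the tests below, those of dilution with another cell type and of a difference between cultures unrelated to Polycomb loss were chosen only after the result was seen, and thinning to equal depth was added after seeing the data.

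Of the genes named in the comparisons with control, 61 differed between the knockouts by the limma test of Eed_KO minus Ezh2_KO, all at adjusted p of 0.0497 or less. Many were named for their change in Ezh2_KO and are tested here against the same Ezh2_KO libraries, which favours a difference. Values are log2. Among epithelial, duct and classical-subtype genes the differences were Anxa10 6.57, Esrp1 6.07, Esrp2 3.97, Foxa2 1.77, Hnf1a 8.55, Hnf1b 2.47, Hnf4a 9.92, Krt19 1.89, Lsr 8.11, Muc1 5.79, Onecut1 5.87, Spint2 3.81 and St14 4.66. Among mesenchymal, fibroblast and other matrix genes they were Col14a1 4.18, Col3a1 -8.3, Mgp -5.07, Pdgfrb -4.84, Snai1 -3.29, Sparc -1.86, Nepn 8.67 and Acan 6.59. Developmental, Wnt, BMP and neuronal genes differed by Axin2 -2.46, Barx2 6.89, Bmp2 -2.52, En1 5.48, Gdf15 -2.28, Hoxa13 4.38, Tgfb3 -1.31 and Tubb3 -2.82. Polycomb subunits differed by Eed -2.77, Ezh1 1.23, Pcgf6 1.3 and Phc2 -1.04, and imprinted genes by Peg3 -10.1 and Phlda2 3.54. For NRF2 targets and genes of metabolism and uptake the values were Gclc 2.35, Me1 1.15, Txn1 -0.98, Hk2 1.79, Pfkp -1.41, Lss 1.35, Hmgcs2 11.73, Pklr 9.32, Cdc42 -0.89 and Rab34 -0.87. For immune and stress genes they were H2-K1 1.76, Irf1 1.84, Cxcl12 -7.76, Il5ra 6.81, Mrc1 2.27, Eda2r -6.71 and Edem1 -1.06. The remaining genes were Anxa13 10.02, Chst2 -9.31, Clca1 8.96, Gimd1 8.5, Krt23 8.58, Rerg 7.03, Scn5a -9.27, Tmtc1 5.25 and Wwc1 2.34.

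By the camera test of the same difference, 8 lists differed in their median log2: duct cell genes 3.6, classical-subtype genes 4.05, epithelial genes 3.81, mesenchymal genes -1.86, interferon genes 0.71, cholesterol synthesis genes 0.61, hepatocyte genes 5.38 and fibroblast genes -4.84. None of these calls held with an estimated correlation.

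Mesenchymal genes were higher and epithelial genes lower in Ezh2_KO than in control. Limma called 13 of 21 mesenchymal genes higher, and of 19 epithelial genes 8 lower and 2 higher. Neither list test passed with an estimated correlation (camera adjusted p = 0.206 for each). Dilution of unchanged parental cells with cells that lack these transcripts is argued against. The epithelial genes that fell kept from 0.378% (Lsr) to 19% (Krt19) of their control level, a 50.3-fold range where such dilution needs a like fraction. Marveld3, at 0 in Ezh2_KO, is left out of it. Cells that express some of these genes could leave an uneven range, so dilution with such cells stays open. Deeper sequencing of the controls is argued against, since 20 of 21 mesenchymal rises and epithelial falls were still called with all libraries thinned to equal reads. A difference between cultures unrelated to Polycomb loss cannot be told apart from loss of EZH2. The edited and control cells are different cultures, and both knockouts were compared with the same 2 controls. The 13 mesenchymal genes that rose had a median of 0.88 in Eed_KO with 2 of them called, which cannot decide the question in this design. Loss of EZH2 beyond that of EED stays open as untested, and so does a difference between clones.

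Myeloid transcripts were high in control replicate 2. In a second list of myeloid genes, written before its values were seen, 21 of 26 were at least 4-fold higher in control replicate 2 than in control replicate 1, and those 21 were highest there of all 6 libraries. Abundant members were Apoe (43.78 and 1843 in the controls), Ctss (21.49 and 1832) and Mpeg1 (24.67 and 1334), while Ctsc, Lgmn, Cd53, Hexb and Mrc1 were not higher, and Lcp1 and Cybb were also present in Eed_KO. Myeloid cells or their RNA mixed into that library are a candidate explanation. No sort or gate is named that would remove them, and no biological explanation was tested.

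Chromosome X genes were lower in control replicate 1 than in replicate 2, by a median of 0.76 on the log2 scale (-0.76). A trend on GC content and transcript length is argued against, since -0.72 was left after removing it. A copy number difference between the cells of the 2 control libraries is a candidate explanation: split at the median gene position, both parts of the chromosome were shifted, by -0.59 and -0.89. A biological explanation within the design was not tested, as both libraries are controls.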

How the results depend on the processing

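Thinning to equal depth was chosen after seeing the data. Among named genes, 2846 of 3479 recomputed values kept direction and side of the threshold, 621 fell short of it, 5 newly passed and 7 changed sign; among lists called, 540 of 593 kept both and 53 fell short, 33 of these with the estimated correlation. The values that changed sign were all of Nfe2l2, never called. The value of Nfe2l2, Ezh2_KO minus control, was 0.15 without control replicate 2 and 0.22 without Ezh2_KO replicate 2 (range -0.602 to 0.218 with a library left out). The value of Nfe2l2, Eed_KO minus control, was 0.11 without control replicate 2 (range -0.562 to 0.114). The value of Nfe2l2, Eed_KO minus Ezh2_KO, was 0.093 with equal totals, 0.11 after quantile normalization, 0.38 without Ezh2_KO replicate 1 and 0.07 without Eed_KO replicate 2 (range -0.443 to 0.378); the cause was not tested.

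With a library left out, genes higher, Ezh2_KO minus control, ran from 267 to 1691, genes higher, Eed_KO minus control, from 0 to 1182 and genes higher, Eed_KO minus Ezh2_KO, from 1 to 1248. The genes lower, Ezh2_KO minus control, ran from 216 to 1187, genes lower, Eed_KO minus control, from 0 to 454 and genes lower, Eed_KO minus Ezh2_KO, from 0 to 1075. There were 0 to 751 genes higher in both knockouts than control and 0 to 273 genes lower in both knockouts than control, and the correlation of fold changes ran from 0.333 to 0.535. Limma gave the counts of 0 without an Eed_KO library, with 2150 or 1975 genes at an unadjusted p under 0.05 in Eed_KO minus control and 2002 in Eed_KO minus Ezh2_KO, and edgeR and DESeq2 were not run without a library. The group with 1 library left was assumed to vary like the others, so these fits have fewer samples. Where that group was not among the 2 compared, no fold change moved and only the variance estimate was altered.

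Other settings moved the counts of genes higher, Ezh2_KO minus control, genes lower, Ezh2_KO minus control, genes higher, Eed_KO minus control, genes lower, Eed_KO minus control, genes higher, Eed_KO minus Ezh2_KO, genes lower, Eed_KO minus Ezh2_KO, genes higher in both knockouts than control, genes lower in both knockouts than control, and the correlation of fold changes. Quantile normalization gave 230 genes higher in both knockouts and a correlation of 0.36. Without an intensity trend 595, 24 and 373 genes were lower in Ezh2_KO minus control, Eed_KO minus control and Eed_KO minus Ezh2_KO, and 16 lower in both knockouts. With the 4 libraries compared alone there were 566 higher and 259 lower in Ezh2_KO minus control, 125 and 7 in Eed_KO minus control, 1038 lower in Eed_KO minus Ezh2_KO, and 56 and 2 in both knockouts. edgeR gave 216 and 45 in Eed_KO minus control, 479 and 303 in Eed_KO minus Ezh2_KO, and 154 and 31 in both knockouts. DESeq2 gave 2174 and 1834 in Ezh2_KO minus control, 1669 and 1156 in Eed_KO minus control, 1469 and 1379 in Eed_KO minus Ezh2_KO, and 939 and 572 in both knockouts. The replicate block gave 620 lower in Ezh2_KO minus control, 257 and 27 in Eed_KO minus control, and 176 and 14 in both knockouts. Across genes, the residuals of same-numbered replicates correlated at 0.0622, -0.114 and -0.0288. These values show no pairing by replicate number, but they cannot exclude a shared batch. Pairing by the numbers in the titles was not tested. A log2 change of at least 1 left 649, 95 and 38 lower in Ezh2_KO minus control, Eed_KO minus control and both, by its construction. For the other settings the cause was not tested.

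Of the calls in Ezh2_KO minus control, 47.8% were higher after quantile normalization, so falls outnumbered rises there, against 51.5% with equal totals and 53.6% with TMM. The camera call of the list Duct cell genes, Eed_KO minus control, also ended without an intensity trend (adjusted p = 0.0597). The median of all genes moved by 0.12 with equal totals in Eed_KO minus Ezh2_KO and by -0.12 with quantile normalization in Eed_KO minus control. Fry ended the list calls of proliferation, cholesterol synthesis, immune cell and ribosomal genes in Ezh2_KO minus control, interferon and ribosomal genes in Eed_KO minus control, and interferon and cholesterol synthesis genes between knockouts. It kept 11 of 15 list calls in Ezh2_KO minus control, 8 of 10 in Eed_KO minus control and 6 of 8 between knockouts. Unlike camera, fry does not compare a list with the other genes. Depth limits genes near the floor of 3 reads, worth 1.36 to 4.62 normalised counts in a library.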

Other observations

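Several lists fixed before the data were examined had no camera call in Ezh2_KO. In the list of PRC2 subunits, Ezh2_KO had 4 of 11 lower and 1 higher (camera adjusted p = 0.251): besides Ezh2 and Suz12, Ezh1, the paralog of Ezh2, fell by 1.36 ± 0.19 and Mtf2 by 0.96, and Phf19, a PRC2 cofactor, rose by 1.98 ± 0.21. Eed_KO had 1 lower (Eed) and 1 higher (Phf19, 1.16; camera adjusted p = 0.0975). Among PRC1 subunits, Cbx4 and Cbx6, chromodomain subunits, rose by 0.99 ± 0.15 and 1.12 ± 0.25 in Ezh2_KO and Pcgf6 fell by 1.59 ± 0.2 (camera adjusted p = 0.28). In Eed_KO, Cbx4 rose by 1.42 ± 0.15, Cbx8 by 1.28 ± 0.24 and Rnf2 by 0.8, and Phc2 fell by 1.03 ± 0.17 (camera adjusted p = 0.0975). Of 14 imprinted genes, Peg3 and Plagl1 (5.4 ± 0.64) rose and Phlda2 fell (-2.9 ± 0.3) in Ezh2_KO, and Plagl1 rose in Eed_KO (7.59); camera adjusted p were 0.167 and 0.187. Cell cycle inhibitors had Cdkn2d higher in Ezh2_KO (1.58; camera adjusted p = 0.293) and 0 called by limma of 5 in Eed_KO (0 before adjustment, with edgeR or with DESeq2; camera adjusted p = 0.767).

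The same held for lists of signalling, uptake and metabolic genes. In Ezh2_KO the cytokine genes Cxcl12 (6.6 ± 1.1) and Csf1 (3.28 ± 0.37) rose and Csf2 (-2 ± 0.32) and Cxcl5 (-6.69) fell, and in Eed_KO Cxcl15 rose (7.25) and Csf2 fell (-1.79); camera adjusted p were 0.533 and 0.154. Of KRAS and MAPK output genes, Egr1 (1.56 ± 0.26), Dusp6 (0.99 ± 0.2) and Spred1 rose in Ezh2_KO and Epha2 (-0.7 ± 0.14), Epha4 and Myc fell, and Spry1 and Egr1 rose in Eed_KO; camera adjusted p were 0.456 and 0.524. Macropinocytosis genes Egfr (3.02 ± 0.5), Rab34 (0.91 ± 0.13) and Cdc42 (0.73 ± 0.17) rose in Ezh2_KO and Egfr in Eed_KO (2.62); camera adjusted p were 0.432 and 0.524. Among glycolysis and hypoxia genes Pfkp (2.86 ± 0.31) and Vegfa (1.43 ± 0.2) rose and Hk2 (-1.79 ± 0.26), Gapdh and Tpi1 fell in Ezh2_KO, and Vegfa and Ndrg1 rose in Eed_KO; camera adjusted p were 0.832 and 0.653. In the unfolded protein and ATF4 response, Hspa5, an endoplasmic reticulum chaperone, rose by 0.89 in Ezh2_KO and 1.31 ± 0.18 in Eed_KO, and Phgdh, a serine synthesis enzyme, fell by 2.08 ± 0.19 and 1.25 ± 0.19. Edem1 (0.76 ± 0.16) rose and Psat1 (-1.27 ± 0.23) fell in Ezh2_KO, and Atf3 rose in Eed_KO (3.63 ± 0.7); camera adjusted p were 0.533 and 0.827. YAP target genes had Arhgef17 (2.78 ± 0.33), Cyr61 (2.24 ± 0.32) and Ctgf higher and Wwc1 (-1.87 ± 0.31) and F3 lower in Ezh2_KO (camera adjusted p = 0.0775). In antigen presentation B2m rose (1.49 ± 0.32) and H2-K1 (-1.38 ± 0.26) and Bst2 (-1.14 ± 0.28) fell in Ezh2_KO (camera adjusted p = 0.326), and 0 of the 35 were called when adjusted over the list alone. Adjusted so, the genes higher and lower in Ezh2_KO were 1 and 4 for PRC2 subunits, 2 and 1 for PRC1 subunits, 3 and 1 for imprinted genes, 3 and 1 for cell cycle inhibitors, 2 and 3 for cytokines, 6 and 3 for KRAS and MAPK output, 4 and 2 for macropinocytosis, 3 and 3 for glycolysis, 3 and 3 for the unfolded protein response and 6 and 2 for YAP targets. In Eed_KO the first 9 of these lists had 1 and 4, 3 and 1, 2 and 0, 0 and 0, 2 and 1, 2 and 0, 1 and 0, 3 and 2, and 4 and 1 by limma. Of the named genes in this part and the one before it, Phf19, Peg3, Phlda2, Csf1, Vegfa and Phgdh kept their Ezh2_KO calls in all 6 fits that left out a library. The other Ezh2_KO calls were lost in at least 1 such fit, and every Eed_KO call was lost without either Eed_KO library.

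Endocrine and neuronal genes in Eed_KO had Uchl1 (5.66) and Map2 (3.59) higher of 10 (camera adjusted p = 0.0798), and cholesterol synthesis genes 0 called by limma of 20 (2 higher and 1 lower before adjustment, 0 with edgeR, 3 with DESeq2; camera adjusted p = 0.784). Mesenchymal genes in Eed_KO had Fn1 (2.51) and Ctgf (1.96 ± 0.36) higher of 21 (camera adjusted p = 0.0975), fibroblast genes Pdgfrb (4.83) of 11 (0.189), and classical-subtype genes Muc13 (4.53) of 21 (0.105). Replication-dependent histone genes had Hist1h1c and Hist1h2bc higher of 8 in Ezh2_KO (1.69 and 2.24) and these (2.14 ± 0.37 and 2.07 ± 0.35) and Hist1h1d (2.2 ± 0.44) in Eed_KO; camera adjusted p were 0.351 and 0.682, and the list medians changed sign under quantile normalization. All of these Eed_KO calls were lost without either Eed_KO library. Adjusted over the list alone, the genes higher and lower in Eed_KO were 4 and 1 for endocrine and neuronal genes, 0 and 0 by limma for cholesterol synthesis, 5 and 0 for mesenchymal, 1 and 0 for fibroblast, 4 and 1 for classical-subtype and 3 and 1 for histone genes (2 and 0 in Ezh2_KO).

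Lists of other cell types were small. Limma called 0 of 7 immune cell genes in Ezh2_KO (3 lower before adjustment, 0 with edgeR, 6 with DESeq2), with a median of -3.61 and camera adjusted p = 0.0188 (adjusted p = 0.524 with an estimated correlation). Without control replicate 2 the immune cell genes had a median of -1.17 and camera adjusted p = 0.18, and without Ezh2_KO replicate 2 camera adjusted p = 0.063. In Eed_KO camera adjusted p was 0.0721. Of 8 endothelial genes limma called 0 against control (3 and 2 higher before adjustment, 0 with edgeR, 2 and 0 with DESeq2; camera adjusted p = 0.0731 and 0.599). Of 5 hepatocyte genes limma called 0 against control (camera adjusted p = 0.155 and 0.148; 2 lower and 1 higher before adjustment, 0 with edgeR, 2 and 0 with DESeq2). Between knockouts Ttr was higher in Eed_KO (7.57; camera adjusted p = 0.0118, adjusted p = 0.31 with an estimated correlation), a call lost without Ezh2_KO replicate 2 or either Eed_KO library. Acinar cell genes had Nr5a2 higher in Eed_KO (7.08) of 4 tested, basal-like genes had 0 called by limma of 3 (1 lower before adjustment in each knockout, 0 with edgeR, 0 and 1 with DESeq2), 3 of 20 germline genes were in the table and 0 were tested, and 0 of 15 mitochondrially encoded symbols matched.

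Between knockouts, cholesterol synthesis genes were higher in Eed_KO in 3 of 20 (camera adjusted p = 6.48e-04, adjusted p = 0.731 with an estimated correlation) and interferon genes in 2 of 35, H2-K1 and Irf1 (camera adjusted p = 0.0263, adjusted p = 0.867 with an estimated correlation). The camera call of the list Interferon response and antigen presentation, Eed_KO minus Ezh2_KO, was lost without Ezh2_KO replicate 1 (0.158) or Eed_KO replicate 1 (0.132), with equal totals (0.0745) and after quantile normalization (0.0586). Chromosome medians were set beside those of 10000 random lists of the same size. Leaving out chromosome Y, 18 of 20 lay outside them in control replicate 1 minus replicate 2, and 4 to 13 in the other differences. Those beyond 0.3 in size follow, with X of the controls given above. In control replicate 1 minus replicate 2 they were 0.38 on chromosome 13, 0.53 on 15 and 0.59 on 19. In Ezh2_KO minus control they were -0.38 on 3, -0.31 on 6, -0.5 on 19 and 0.39 on X, and in Eed_KO minus control 0.33 on 1, -0.38 on 8 and 0.37 on 14. In Eed_KO minus Ezh2_KO they were 0.33 on 1, 0.34 on 3, -0.54 on 4 and -0.53 on X, and in Ezh2_KO replicate 1 minus replicate 2 -0.43 on 14 and 0.36 on 15. Counted against all 5 other libraries, control replicate 1 had 14 genes at least 4-fold above and 287 at least 4-fold below, and control replicate 2 had 39 and 147. The knockout libraries had 12 to 94 above and 0 to 85 below. Some genes high in control replicate 2 alone are not myeloid genes, such as Sprr1a, a squamous cell gene (794.3 and 32600 in the controls).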
